A study of Marchantia polymorpha and Lactuca sativa with 27 samples.

How the data were processed

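RNA was measured by sequencing poly(A)-selected, directional libraries from whole Marchantia polymorpha plants (a liverwort) and from shoots of the lettuce Red fire, per the labels' protocols. The submitters' processing notes name STAR 2.7, a read aligner, and DESeq2, without saying what each was used for. The program that assigned reads to genes, its strand setting, its treatment of reads that match several genes and the genome builds were not given in the sources used here. Reads from overlapping or antisense genes, and from close members of large families such as the peroxidases and polyphenol oxidases, may therefore have been divided between genes in ways that cannot be traced, and values of single family members are uncertain to that extent.

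The deposited values were counts of reads per gene, 1 table for each species, per the file headers and the whole-number values, which summed to a different total in each library. No normalization of these counts by the authors was found. The Marchantia table held 19355 genes, of which 2175 were at 0 in all 18 libraries, and the lettuce table held 48985 genes, of which 18837 were at 0 in all 9 libraries. Every column of counts was used. The lettuce full-medium columns carried numbers other than those in the sample titles, so these 3 libraries were used as replicates without a number. Totals ran from 18165419 to 25544702 counts per Marchantia library and from 18857111 to 22642271 per lettuce library, so that 1 count was worth 0.0391 to 0.055 CPM (counts scaled to the library total) in Marchantia. Replicate pairs all differed by more than sampling noise, with chi-square values of 3.55 to 21.2 per degree of freedom over genes of at least 20 counts in Marchantia and 5.06 to 27.9 in lettuce, so no library was treated as a second copy of another.

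Libraries were grouped by the labels into 6 Marchantia groups and 3 lettuce groups of 3 libraries each. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. For each species, 1 edgeR model was fitted to all libraries so that groups shared 1 estimate of the spread (edgeR 4.0.16 in R 4.3.3). Low genes were removed with filterByExpr, which left 13016 Marchantia and 23366 lettuce genes. TMM normalization gave factors of 0.972 to 1.06 and 0.966 to 1.03, and the common biological coefficient of variation was 0.0962 and 0.123. Each comparison was a contrast tested with the robust quasi-likelihood F-test (two-sided), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called; every adjusted p of a gene in the report comes from this test. Standard errors (SE) are those implied by the log2 fold change and the F statistic. Levels are CPM with TMM-scaled library sizes, as mean ± SD over the 3 libraries of a group.

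Gene names came from a table of names for the assembly MpTak2_v7.1, of which only the names and locus numbers were used. Its locus numbers were matched to the identifiers of the count table, which assumes that both number genes alike, since the authors' build is not known. Of its 18391 entries 17384 were matched, and 2441 of the tested genes had a symbol. Neither the table nor the files pair lettuce identifiers with names, so the gene lists could not be applied to lettuce and at most 2 identifiers are given in each direction. Named genes followed a rule set, like the choice of comparisons, tests and alternatives, before the data were examined. It took MpWRKY10, the 10 largest rises and 10 largest falls among called genes with a name, a mean of at least 1 CPM over all libraries and no overlap between the groups compared (a demand not made of interactions), and up to 4 members with the smallest adjusted p of each list. A symbol stood in for the gene description that the rule had foreseen. The order of neighbouring genes was read from the chromosome and locus numbers in the identifiers of the count table.

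The 41 gene lists covered nutrient transport and signalling, phenolic and terpene metabolism, cell walls, defence, photosynthesis, cell division, transcription factor families and markers of other tissues. Topics such as nutrient transport, phenolic and terpene enzymes, photosynthesis, histones and WRKY factors were set in advance. Other lists were not in that plan, among them expansins, cupins, LEA, GH16, lectin receptor kinases, P450, oil-body markers, ABCG, bHLH, ERF and NAC. Some planned topics, such as ribosomal proteins, had no list. The patterns that pick members were adapted to the symbols of the name table before any test. A list was tested as a whole with camera (limma 3.58.1) on voom log2 CPM, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 41 lists of a comparison, and again with an estimated correlation and with fry. Counts of called members are given over all genes tested and adjusted over the list alone.

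A gene at 0 counts in a group was compared with a floor of 3 counts over that group and is given as at least N-fold higher or lower. A gene with 1 to 3 counts in a group is given as a ratio with a 95% exact binomial interval. These floors and intervals cover counting error only, because reads without molecular identifiers are not independent molecules. Overlaps between starvations that share controls were set against 20 simulations of unchanged groups and against independent lists.

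Alternatives were DESeq2 size factors within edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, the replicate number as a block, a fit of only the groups compared, a 2-fold minimum, and leaving out each library in turn. After the data were seen, fits without an abundant gene and without libraries that stood apart were added. The procedure was tested on simulated counts with 200 changed genes. For the wild-type phosphate comparison, 93.9% of 4-fold, 77.6% of 2-fold and 74.6% of 1.5-fold changes were recovered among 12861 genes, and 4.09% of calls were false. The interaction for nitrate recovered 87.9%, 68.7% and 49.3% among 12858 genes, with 10.5% false calls. The lettuce phosphate comparison recovered 92.4%, 70.1% and 40.3% among 23122 genes, with 7.53% false calls.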

Results

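The data were RNA-seq counts from 27 libraries. In Marchantia, the wild type Tak-1 and the mutant line labelled Mpwrky10, named for a transcription factor gene of the WRKY family, were compared as whole plants. Gemmalings, which are young plants grown from asexual gemmae, were 7 days old when moved for 5 days to full medium with 2 mM phosphate and 10 mM nitrate, to medium with 0 mM phosphate or to medium with 0 mM nitrate. Lettuce seedlings of the red-leaved Red fire were moved to the same 3 media at 4 days of age, and their shoots were taken after 7 days. Each of the 9 groups held 3 libraries. Depth was 18165419 to 25544702 counts per library in Marchantia and 18857111 to 22642271 in lettuce. On the first principal component, which held 43.5% of the variance in Marchantia, wild-type replicate 1 labelled no nitrate lay at 18.6 against 43.5 and 39.3 for its partners. Wild-type replicate 3 in full medium lay at -39.2 against -54.5 and -51.5. Mutant replicate 3 in full medium lay at -67.3 against -50.3 and -51.0, and the mutant libraries labelled no phosphate were spread over 8.5, 23 and -3.6. In lettuce the third full-medium column lay at -36.4 against -59.2 and -65.2 on the first component (58.3% of the variance).

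MpWRKY10 (Mp7g06550), the targeted gene, was measured at 19.6 ± 2.61 CPM in the wild type and 18.7 ± 3.45 CPM in the mutant in full medium (SD, 3 libraries each). In the libraries labelled no phosphate the levels were 29.8 ± 1.34 and 27.2 ± 1.68 CPM, and in those labelled no nitrate 23.5 ± 2.91 and 35.8 ± 1.65 CPM. The mutant was higher only in the libraries labelled no nitrate (log2 0.60, SE 0.117, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.00138). In full medium and in the libraries labelled no phosphate the adjusted p was 0.864 and 0.515. The kind of mutation is not given in the labels, and many mutations leave the transcript in place, so these levels check nothing about the genotype labels.

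To ask how the wild type responds to phosphate removal, libraries labelled no phosphate were compared with full medium. Ammonium transporter genes of the AMT family, which import ammonium, were higher in the libraries labelled no phosphate, and the small subunit of Rubisco (MpRBCS), which takes part in carbon fixation, was lower. MpAMT2.4 rose from 0.305 ± 0.0507 to 40.4 ± 6.10 CPM (log2 7.00, SE 0.726, adjusted p = 4.83e-06), and MpRBCS fell from 399 ± 38.1 to 124 ± 3.19 CPM (log2 -1.69, SE 0.0957, adjusted p = 1.46e-09). The UDP-glycosyltransferase gene MpUGT36, of a family that attaches sugars to small molecules, rose from 3.44 ± 0.740 to 178 ± 13.9 CPM. The peroxidase gene MpPOD55 was at least 163-fold higher and the lectin receptor kinase gene MpRLK-Pelle_L-LEC17 at least 93.4-fold higher. Among the largest falls were MpExpansin34, of a family that loosens cell walls (log2 -4.46, SE 0.217), the polyphenol oxidase MpPPO42 (log2 -3.05, SE 0.244), the dirigent protein gene MpDIR48 (log2 -2.96, SE 0.356) and MpASLBD24 (log2 -2.78, SE 0.170).

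In all, 3417 genes rose and 2979 fell, of which 1104 and 281 changed at least 2-fold, and over all tested genes 60.6% had no overlap between the groups, against 10% by chance. Of the 41 lists, 9 were called by camera. Of 109 class III peroxidase genes, whose secreted enzymes act on phenolic compounds and cell walls, 86 rose and 8 fell (86 and 8 adjusted over the list alone, median log2 2.97, or 2.92 with genes at 0 held at their bound, camera adjusted p = 7.22e-12), among them MpPOD18 (log2 6.76) and MpPOD149 (log2 1.78). All 8 AMT genes rose (8 adjusted over the list alone, median 3.84, adjusted p = 0.00159), including MpAMT1.5 (log2 5.71) and MpAMT1.3 (log2 5.60). Of 16 terpene synthase genes 12 rose and 0 fell (12 and 1 adjusted over the list alone, adjusted p = 8.35e-05), among them MpTPS6 (log2 3.91) and MpTPS5 (log2 2.02). Of 16 early phenylpropanoid genes, which lead from phenylalanine to phenolic acids, 9 rose and 1 fell (10 and 1 adjusted over the list alone, adjusted p = 0.0208), with MpPAL1 at log2 1.48 and MpC4H3 at 1.47. With an estimated correlation these 4 lists had adjusted p = 0.555, 0.512, 0.512 and 0.574.

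Of 21 autophagy genes, which recycle cell contents, 13 rose and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 0.0133), with MpATG8a at log2 0.49 and MpATG3 at 0.47. Cytochrome P450 genes rose in 38 and fell in 17 of 85 cases (39 and 18 adjusted over the list alone, adjusted p = 0.0208), with MpCYP704-like5 at log2 1.54. UDP-glycosyltransferase genes rose in 15 and fell in 3 of 30 cases (15 and 4 adjusted over the list alone, adjusted p = 0.0282), with MpUGT2 at 1.47. All 5 chlorophyll and photosynthesis genes fell (5 adjusted over the list alone, adjusted p = 0.000436), including the magnesium chelatase genes MpCHLI1/2-like (log2 -0.66) and MpCHLD (log2 -0.52). Of 41 histone and DNA replication genes 25 fell and 0 rose (27 and 0 adjusted over the list alone, median -0.24, adjusted p = 7.02e-05), with MpH2B.6 at -0.38 and MpMCM at -0.46. These 5 lists had adjusted p = 0.574, 0.512, 0.555, 0.512 and 0.555 with an estimated correlation. The 7 phosphate transporter genes of the PTB family were not called as a list, with 1 higher, 0 lower and 6 not called (1 and 0 adjusted over the list alone, median 0.00, camera adjusted p = 0.766, and adjusted p = 0.872 with an estimated correlation). MpPTB7 rose (log2 1.08, SE 0.225), while MpPTB8 had 21.6 ± 1.73 against 31.8 ± 8.45 CPM in full medium (adjusted p = 0.0915).

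**Figure D1:**
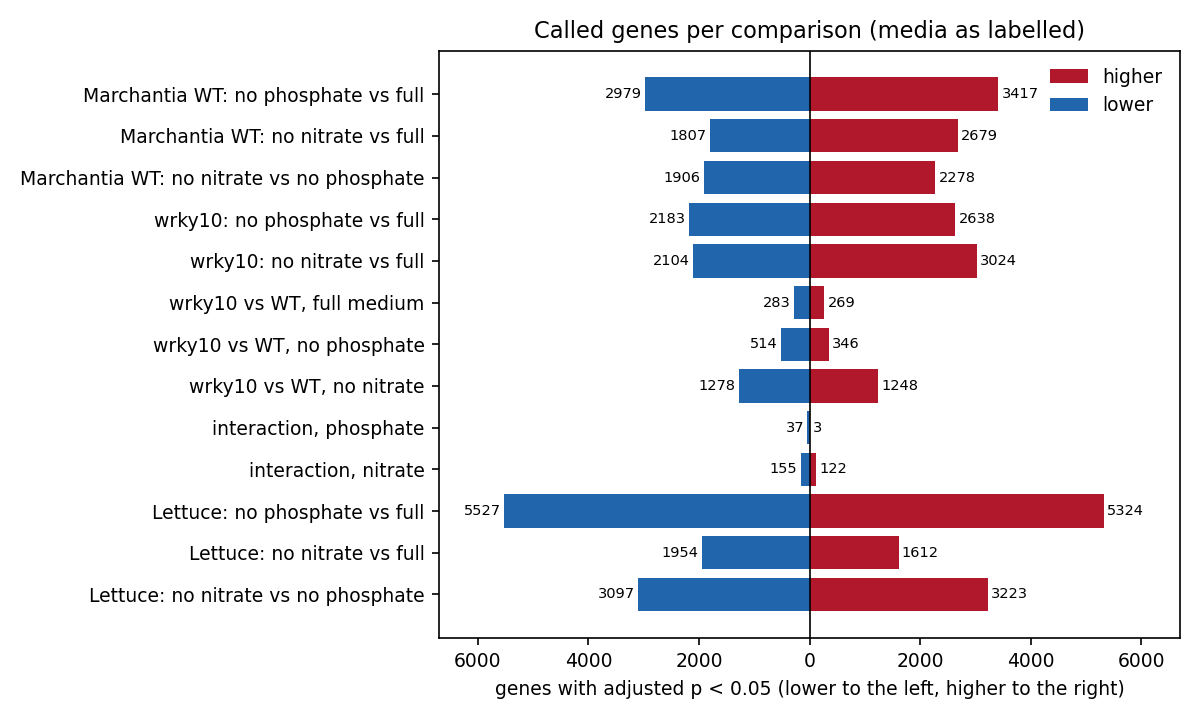
Number of genes called higher (bars to the right) and lower (bars to the left) in each comparison with edgeR's quasi-likelihood test, Marchantia and lettuce. The counts run from 40 genes for the difference in phosphate response between genotypes to 10851 for phosphate removal in lettuce.

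Nitrate removal was asked about in the same way, with libraries labelled no nitrate against full medium. Phosphate transporter genes of the PTB family, which import phosphate, rose in these libraries. MpPTB8 rose from 31.8 ± 8.45 to 337 ± 73.9 CPM (log2 3.41, SE 0.257, adjusted p = 8.1e-07), MpPTB5 was at least 310-fold, MpPTB1 at least 200-fold and MpPTB2 at least 76.4-fold higher. Some other genes known to respond to phosphate shortage were also higher: MpSPX, of a family of phosphate sensors (log2 0.82, SE 0.0772), the glycerophosphodiesterase MpGDPD (log2 2.14, SE 0.217; 493 ± 13.4 against 112 ± 18.7 CPM) and the sulfolipid synthesis gene MpSQD (log2 0.89, SE 0.0955). The galactolipid synthesis gene MpMGDG was not, at 99.5 CPM against 103.1 CPM in full medium. Of 8 genes of phosphate signalling and scavenging, 2 rose, 4 fell and 2 were not called (2 and 4 adjusted over the list alone, median -0.31, camera adjusted p = 0.565, adjusted p = 0.613 with an estimated correlation). The pathogenesis-related gene MpPR1o rose from 0.711 ± 0.330 to 70.5 ± 21.7 CPM (log2 6.56, SE 0.632), and the polyphenol oxidase MpPPO32 from 9.09 ± 1.53 to 124 ± 11.6 CPM (log2 3.76, SE 0.136, adjusted p = 7.42e-12). The largest falls were in MpLPR7, a multicopper oxidase relative (log2 -1.87, SE 0.158), and MpExpansin34 (log2 -1.30, SE 0.173).

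Here 2679 genes rose and 1807 fell, 1044 and 64 of them at least 2-fold, and 49.6% of all tested genes had no overlap between the groups (10% by chance). Of the 41 lists, 18 were called by camera, and none held with an estimated correlation. All 7 PTB genes rose (7 adjusted over the list alone, median log2 9.20, or 6.26 with genes at 0 held at their bound, camera adjusted p = 1.79e-05, adjusted p = 0.198 with an estimated correlation). Of 9 genes of membrane lipid remodelling, which replaces phospholipids, 7 rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 0.0068), with MpPLD7 at log2 3.47. Of 109 peroxidase genes 81 rose and 1 fell (84 and 1 adjusted over the list alone, median 2.68, or 2.60 at the bound, adjusted p = 4.3e-17), among them MpPOD94 (log2 5.21) and MpPOD165 (log2 0.80). Of 33 polyphenol oxidase genes, which oxidise phenolic compounds, 19 rose and 4 fell (20 and 5 adjusted over the list alone, adjusted p = 0.000269), with MpPPO56 at log2 1.75. These 3 lists had adjusted p = 0.198 with an estimated correlation. Of 21 chalcone synthase family genes, which begin flavonoid synthesis, 14 rose and 1 fell (15 and 1 adjusted over the list alone, adjusted p = 0.0032), with MpPKS/CHS-like3 at log2 1.70. Of 16 early phenylpropanoid genes 10 rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 0.00459), with MpC4H3 at 1.59 and MpPAL1 at 1.20. Their adjusted p was 0.378 and 0.348 with an estimated correlation.

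Of 38 dirigent genes, which guide phenolic coupling, 18 rose and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 3.75e-05), with MpDIR9 at log2 1.42. Terpene synthases rose in 12 and fell in 0 of 16 cases (12 and 0 adjusted over the list alone, adjusted p = 0.000134), with MpTPS6 at log2 4.28. GH16 xyloglucan genes rose in 13 and fell in 0 of 24 cases (13 and 0 adjusted over the list alone, adjusted p = 0.00301), with MpGH16.32 at log2 1.96. Lipoxygenases, which make oxylipins, rose in 8 and fell in 0 of 11 cases (8 and 0 adjusted over the list alone, adjusted p = 0.00301), with MpLOX3 at 2.17. Chitinase genes rose in 10 and fell in 1 of 19 cases (12 and 1 adjusted over the list alone, adjusted p = 0.00438), with MpGH19.3 at 4.85. These 5 lists had adjusted p = 0.198 with an estimated correlation. Pathogenesis-related genes rose in 7 and fell in 0 of 16 cases (8 and 0 adjusted over the list alone, median 2.48, or 1.72 at the bound, adjusted p = 0.00644). Lectin receptor kinases rose in 9 and fell in 0 of 16 cases (9 and 1 adjusted over the list alone, adjusted p = 0.00769). Expansins rose in 15 and fell in 2 of 27 cases (16 and 2 adjusted over the list alone, adjusted p = 0.0131). LEA genes, which protect cells from drying, rose in 13 and fell in 3 of 36 cases (13 and 3 adjusted over the list alone, adjusted p = 0.0265). AMT genes rose in 6 and fell in 0 of 8 cases (6 and 0 adjusted over the list alone, adjusted p = 0.0283). Adjusted p with an estimated correlation was 0.348, 0.318, 0.348, 0.318 and 0.348. Of 5 chlorophyll and photosynthesis genes 4 fell and 0 rose (4 and 0 adjusted over the list alone, adjusted p = 0.0265), with MpGUN5 at -0.32. Of 41 histone and replication genes 13 fell and 0 rose (13 and 0 adjusted over the list alone, adjusted p = 3.47e-05), with MpMCM7 at -0.47. Both were lost with an estimated correlation (adjusted p = 0.378 and 0.318).

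The direct difference between the libraries labelled no nitrate and no phosphate in the wild type does not involve the shared controls. MpPTB4 was at least 1080-fold, MpPTB5 at least 325-fold and MpPTB1 at least 210-fold higher in the libraries labelled no nitrate, and MpPTB8 was 337 ± 73.9 against 21.6 ± 1.73 CPM (log2 3.96, SE 0.266, adjusted p = 2.71e-07). MpUGT36 (log2 -4.61, SE 0.306), MpAMT1.5 (log2 -3.16, SE 0.444), MpAMT1.4 (log2 -2.92, SE 0.463), the proton pump gene MpHA11 (log2 -2.94, SE 0.429) and MpNLA, of a family of ubiquitin ligases that act on transporters (log2 -2.77, SE 0.286), were lower there. A total of 2278 genes were higher and 1906 lower in the libraries labelled no nitrate, 451 and 225 of them at least 2-fold, and 49.4% of all tested genes had no overlap (10% by chance). Of 7 PTB genes 6 were higher (6 adjusted over the list alone, median log2 5.00, camera adjusted p = 0.000455), and of 8 AMT genes 5 were lower (5 adjusted over the list alone, median -1.56, adjusted p = 0.00415). Dirigent genes were higher in 17 and lower in 1 of 38 cases (19 and 1 adjusted over the list alone, adjusted p = 0.00415). Chitinases were higher in 9 and lower in 1 of 19 cases (9 and 1 adjusted over the list alone, adjusted p = 0.0103). Antioxidant enzymes were higher in 9 and lower in 1 of 23 cases (9 and 1 adjusted over the list alone, adjusted p = 0.0344) and chlorophyll genes in 4 and 0 of 5 cases (4 and 0 adjusted over the list alone, adjusted p = 0.00452). Autophagy genes were higher in 1 and lower in 9 of 21 cases (1 and 9 adjusted over the list alone, adjusted p = 0.0103) and terpene synthases in 2 and 5 of 16 (2 and 5 adjusted over the list alone, median -0.33, adjusted p = 0.0467). The adjusted p of these 8 lists was 0.403 to 0.612 with an estimated correlation.

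**Figure D2:**
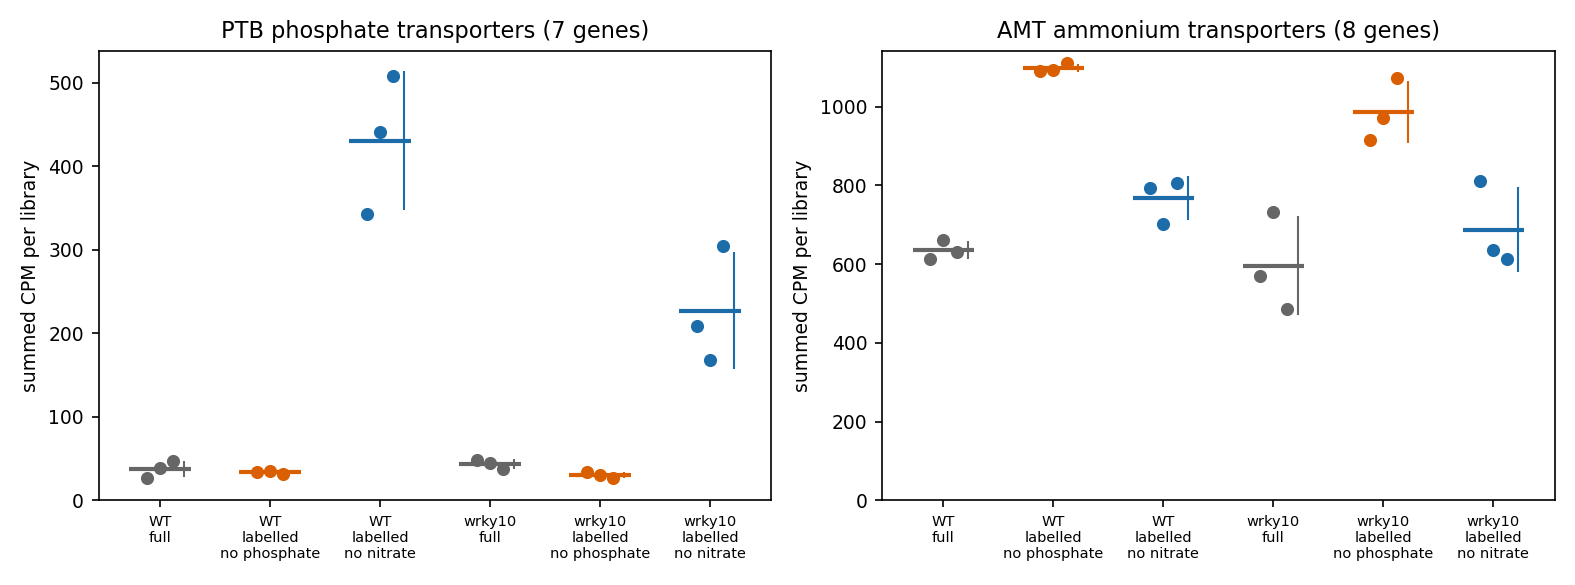
Summed level of the PTB phosphate transporter genes and of the AMT ammonium transporter genes in each Marchantia library, in CPM, by genotype and labelled medium; lines are group means and bars SD over 3 libraries. The PTB sum was 430 ± 83.3 CPM in the wild type labelled no nitrate against 33.7 ± 1.66 CPM labelled no phosphate, and the AMT sum was 767 ± 56.0 against 1097 ± 11.1 CPM.

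In the mutant, 2638 genes were higher and 2183 lower in the libraries labelled no phosphate than in full medium, 794 and 206 of them at least 2-fold, and 44.4% of all tested genes had no overlap (10% by chance). MpAMT2.4 rose from 0.149 ± 0.145 to 11.8 ± 7.21 CPM (log2 6.33, SE 0.874) and MpRBCS fell from 432 ± 39.7 to 153 ± 20.1 CPM (adjusted p = 1.44e-08). MpExpansin34 (log2 -4.08, SE 0.226), MpDIR48 (log2 -3.69, SE 0.382) and MpPPO42 (log2 -2.19, SE 0.235) fell, as in the wild type. MpPTB7 rose (log2 0.99, SE 0.228, adjusted p = 0.00223) and MpPTB8 fell (log2 -0.93, SE 0.261, adjusted p = 0.013). Of 109 peroxidase genes 66 rose and 7 fell (68 and 7 adjusted over the list alone, median log2 2.47, or 2.27 at the bound, camera adjusted p = 1.99e-08), with MpPOD4 at log2 5.84. Of 8 AMT genes 7 rose and 0 fell (7 and 0 adjusted over the list alone, median 2.33, adjusted p = 0.0157), and all 5 chlorophyll and photosynthesis genes fell (5 adjusted over the list alone, median -0.55, adjusted p = 5.33e-05). These were the 3 lists called of 41, each with adjusted p = 0.745 with an estimated correlation.

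In the mutant libraries labelled no nitrate, 3024 genes were higher and 2104 lower than in full medium, 1103 and 124 of them at least 2-fold, and 47.3% of all tested genes had no overlap (10% by chance). MpPR1o rose from 0.319 ± 0.140 to 142 ± 81.3 CPM (log2 8.79, SE 0.705), MpGH19.3 from 4.24 ± 1.51 to 250.4 ± 126 CPM (log2 5.87, SE 0.618) and MpPTB8 from 38.1 ± 5.02 to 201 ± 60.6 CPM (log2 2.41, SE 0.248). Of 16 pathogenesis-related genes 12 rose and 0 fell (13 and 0 adjusted over the list alone, median log2 3.77, camera adjusted p = 2.82e-05), with MpPR6a at 3.46. Of 13 WRKY genes 10 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.50, adjusted p = 0.00167), with MpWRKY7 at 4.51 and MpWRKY8 at 1.07. Of 7 PTB genes 6 rose and 0 fell (6 and 0 adjusted over the list alone, median 6.63, or 4.42 at the bound, adjusted p = 0.00167). Dirigent genes rose in 23 and fell in 1 of 38 cases (23 and 1 adjusted over the list alone, adjusted p = 2.13e-05), with MpDIR9 at log2 2.11. Lipoxygenases rose in 9 and fell in 1 of 11 cases (9 and 1 adjusted over the list alone, adjusted p = 0.0066), with MpLOX1 at log2 3.58. Chitinases rose in 12 and fell in 1 of 19 cases (13 and 2 adjusted over the list alone, adjusted p = 0.00757). Adjusted p of these 6 lists was 0.305 with an estimated correlation. Peroxidases rose in 79 and fell in 2 of 109 cases (83 and 3 adjusted over the list alone, adjusted p = 6.66e-10). Chalcone synthase genes rose in 17 and fell in 1 of 21 cases (17 and 1 adjusted over the list alone, adjusted p = 5.84e-05), with MpPKS/CHS13 at log2 5.84. Early phenylpropanoid genes rose in 11 and fell in 1 of 16 cases (13 and 1 adjusted over the list alone, adjusted p = 0.00167), with MpC4H1 at log2 1.72. Lectin receptor kinases rose in 11 and fell in 1 of 16 cases (11 and 1 adjusted over the list alone, adjusted p = 0.0331). Histone and replication genes rose in 1 and fell in 19 of 41 cases (2 and 24 adjusted over the list alone, adjusted p = 2.82e-05), and all 5 chlorophyll genes fell (5 adjusted over the list alone, adjusted p = 0.00112). With an estimated correlation the adjusted p was 0.397 for 5 of these lists and 0.36 for the chlorophyll genes.

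**Figure D3:**
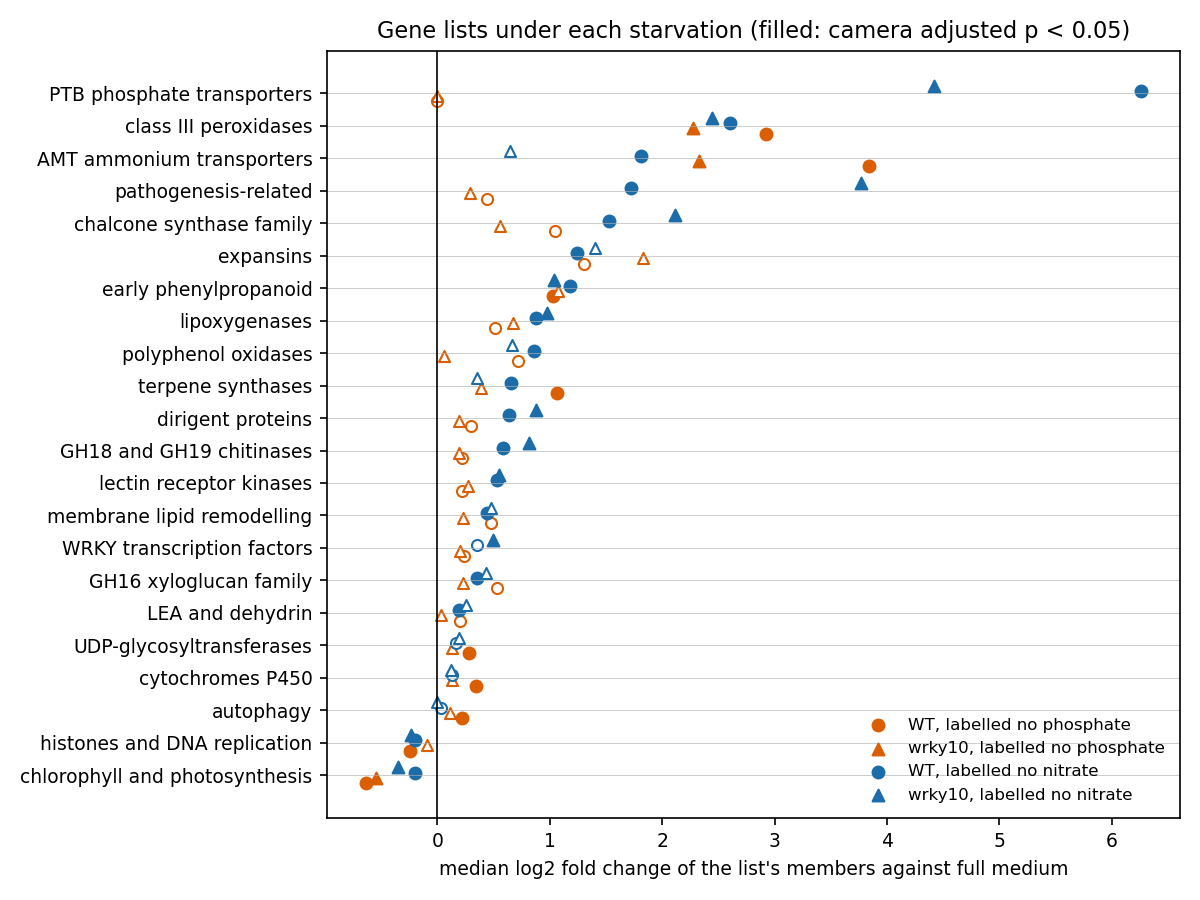
Median log2 fold change of gene lists in the Marchantia comparisons, with genes at 0 counts held at their bound; filled marks are lists with a camera adjusted p under 0.05 at the preset correlation. Peroxidase medians were 2.92 in the wild type labelled no phosphate and 2.60 labelled no nitrate, and the PTB median was 0.00 and 6.26.

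The next comparisons asked what differs between mutant and wild type within a medium. In full medium the terpene synthase gene MpFTPSL2 was at 0.225 ± 0.0558 CPM in the mutant against 16.9 ± 2.34 CPM (log2 -6.22, SE 0.189, adjusted p = 2.18e-14), and MpMTPSL2 at 0.672 ± 0.140 against 17.5 ± 4.25 CPM (log2 -4.69, SE 0.191). The transporter gene MpNPF24, of a family that moves nitrate and peptides, was at least 136-fold lower, and MpCPT5 had a ratio of 493 (counting interval 88.1 to 19500) in favour of the wild type. The polyphenol oxidases MpPPO8 (log2 -6.33, SE 0.284), MpPPO9 (log2 -5.69, SE 0.199) and MpPPO17 (log2 -2.54, SE 0.0858) were lower, and MpDIR2 (log2 2.63, SE 0.301) and MpLOX16 (log2 2.04, SE 0.334) higher. The unnamed gene Mp7g01940, singled out after its values were seen, took 2.51 to 3.45% of all counts in the mutant's 9 libraries and 0.0349 to 0.0491% in those of the wild type, and was 60.8-fold higher in full medium (log2 5.93, SE 0.0975, adjusted p = 7.64e-19), 91.0-fold in the libraries labelled no phosphate and 79.9-fold in those labelled no nitrate.

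In full medium 269 genes were higher and 283 lower, 57 and 116 of them at least 2-fold, and 18.9% of all tested genes had no overlap (10% by chance). Of 33 polyphenol oxidase genes 3 were higher and 8 lower (3 and 9 adjusted over the list alone, median log2 -0.42, camera adjusted p = 3.44e-06), and of 27 expansins 0 and 2 (0 and 5 adjusted over the list alone, adjusted p = 0.000382), with MpExpansin32 at -0.82. Chitinases were lower in 3 of 19 cases (8 adjusted over the list alone, adjusted p = 0.00267), with MpGH18.3 at -1.66, and terpene synthases in 3 of 16 (4 adjusted over the list alone, median -0.10, mean -1.17, adjusted p = 0.0254). These 4 lists had adjusted p = 0.194, 0.49, 0.194 and 0.62 with an estimated correlation. The count of 552 depended on single libraries: it was 265 without wild-type replicate 1, 307 without wild-type replicate 2 and 332 without mutant replicate 3. A fit of these groups alone gave 280. More genes were lower than higher in each of these, such as 94 higher and 171 lower without wild-type replicate 1, 130 and 202 without mutant replicate 3, and 108 and 172 in the fit of these groups alone. Their balance was near even in all libraries and turned slightly with DESeq2 size factors (276 and 275), the DESeq2 Wald test (353 and 351), without Mp7g01940 (281 and 271) and without wild-type replicate 3 (271 and 261). It turned likewise with the replicate block (336 and 324) and without both wild-type libraries that stood apart (302 and 271).

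In the libraries labelled no phosphate, 346 genes were higher and 514 lower in the mutant, 53 and 184 of them at least 2-fold, and 31.1% of all tested genes had no overlap (10% by chance). MpFTPSL2 was at 0.147 ± 0.0862 against 40.4 ± 1.66 CPM (log2 -8.04, SE 0.194), MpNPF24 was at least 334-fold lower, and the P450 gene MpCYP822-like7 was at 8.24 ± 0.671 against 78.3 ± 0.827 CPM (log2 -3.25, SE 0.0946). MpLOX16 (log2 3.12, SE 0.431) and MpPPO32 (log2 1.72, SE 0.144) were higher. Peroxidases were higher in 5 and lower in 21 of 109 cases (8 and 54 adjusted over the list alone, median -0.99, camera adjusted p = 6.67e-16) and AMT genes lower in 4 of 8 (6 adjusted over the list alone, median -1.97, adjusted p = 1.95e-05), with MpAMT2.3 at -2.18. Polyphenol oxidases were higher in 2 and lower in 9 of 33 cases (6 and 12 adjusted over the list alone, adjusted p = 1.07e-06). Terpene synthases were higher in 0 and lower in 5 of 16 cases (1 and 6 adjusted over the list alone, adjusted p = 6.31e-07) and P450 genes in 2 and 14 of 85 (3 and 18 adjusted over the list alone, adjusted p = 0.000747). Of 4 oil-body markers, which mark the cells that store terpenes, 3 were lower (4 adjusted over the list alone, adjusted p = 0.000831): MpR2R3-MYB2 (log2 -0.90), MpERF13 (-0.73) and MpSYP12B (-0.48), with MpC1HDZ at -0.22 (adjusted p = 0.143). The call of MpERF13 ended without a filter on low counts. With an estimated correlation the peroxidases had adjusted p = 0.203 and the other 5 lists 0.0912.

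Histone and replication genes were higher in 9 and lower in 0 of 41 cases (13 and 0 adjusted over the list alone, median log2 0.20, camera adjusted p = 3.13e-09, adjusted p = 0.148 with an estimated correlation), with MpH3.1c at 0.35. Expansins were higher in 1 and lower in 3 of 27 cases (1 and 7 adjusted over the list alone, adjusted p = 0.00121). Chitinases were higher in 0 and lower in 5 of 19 cases (0 and 6 adjusted over the list alone, adjusted p = 0.00663), and GH16 genes in 2 and 4 of 24 (2 and 7 adjusted over the list alone, adjusted p = 0.00715). Cupins were higher in 0 and lower in 5 of 29 cases (0 and 9 adjusted over the list alone, adjusted p = 0.00715) and NPF transporters in 0 and 5 of 21 (1 and 7 adjusted over the list alone, adjusted p = 0.00991). The 21 chalcone synthase genes had a median of -0.44, with 0 called in either direction (0 adjusted over the list alone, adjusted p = 0.0242). With an estimated correlation these 6 lists had adjusted p = 0.222, 0.132, 0.203, 0.0912, 0.203 and 0.68. The count of 860 fell to 352 without wild-type replicate 1, 455 without wild-type replicate 2 and 423 without mutant replicate 3.

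In the libraries labelled no nitrate, 1248 genes were higher and 1278 lower in the mutant, 231 and 268 of them at least 2-fold, and 36.6% of all tested genes had no overlap (10% by chance). Without mutant replicate 2 the count was 1635 in place of 2526. Higher and lower genes were again close, and their balance turned without mutant replicate 1 (1139 and 1097) or 3 (1079 and 1062) or wild-type replicate 2 (900 and 893). MpCPT5 was at least 180-fold and MpNPF24 at least 140-fold lower, and MpPPO3 (log2 3.92, SE 0.505), MpPR6c (log2 3.21, SE 0.470) and MpWRKY7 (log2 2.89, SE 0.491) were higher. Of 7 PTB genes 6 were lower (7 adjusted over the list alone, median log2 -1.84, camera adjusted p = 6.92e-06), with MpPTB4 at 9.45 ± 6.63 against 47.4 ± 4.31 CPM. Of 13 WRKY genes 9 were higher and 0 lower (9 and 0 adjusted over the list alone, median 0.44, adjusted p = 0.000152). Polyphenol oxidases were higher in 5 and lower in 17 of 33 cases (5 and 18 adjusted over the list alone, adjusted p = 3.22e-06). Terpene synthases were higher in 0 and lower in 5 of 16 cases (0 and 5 adjusted over the list alone, adjusted p = 5.74e-05) and cupins in 2 and 10 of 29 (3 and 11 adjusted over the list alone, adjusted p = 0.017). These 5 lists had adjusted p = 0.169 with an estimated correlation.

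Peroxidases were higher in 10 and lower in 34 of 109 cases in the mutant labelled no nitrate (11 and 47 adjusted over the list alone, median log2 -0.95, camera adjusted p = 1.6e-06). Expansins were higher in 2 and lower in 10 of 27 cases (2 and 11 adjusted over the list alone, adjusted p = 0.00358), and GH16 genes in 1 and 6 of 24 (1 and 8 adjusted over the list alone, adjusted p = 0.00948). AMT genes were higher in 0 and lower in 2 of 8 cases (0 and 5 adjusted over the list alone, adjusted p = 0.0206). Pathogenesis-related genes were higher in 9 and lower in 3 of 16 cases (11 and 3 adjusted over the list alone, median 2.04, adjusted p = 0.0234), with MpPR6a at 2.24 and MpPR1m at -1.59. Dirigent genes were higher in 13 and lower in 4 of 38 cases (18 and 6 adjusted over the list alone, adjusted p = 0.017). Chalcone synthase genes were higher in 8 and lower in 1 of 21 cases (8 and 2 adjusted over the list alone, adjusted p = 0.0125), with MpPKS/CHS12 at 2.07. All 7 lists lost the call with an estimated correlation, at adjusted p = 0.542, 0.398, 0.274, 0.445, 0.542, 0.542 and 0.622.

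**Figure D4:**
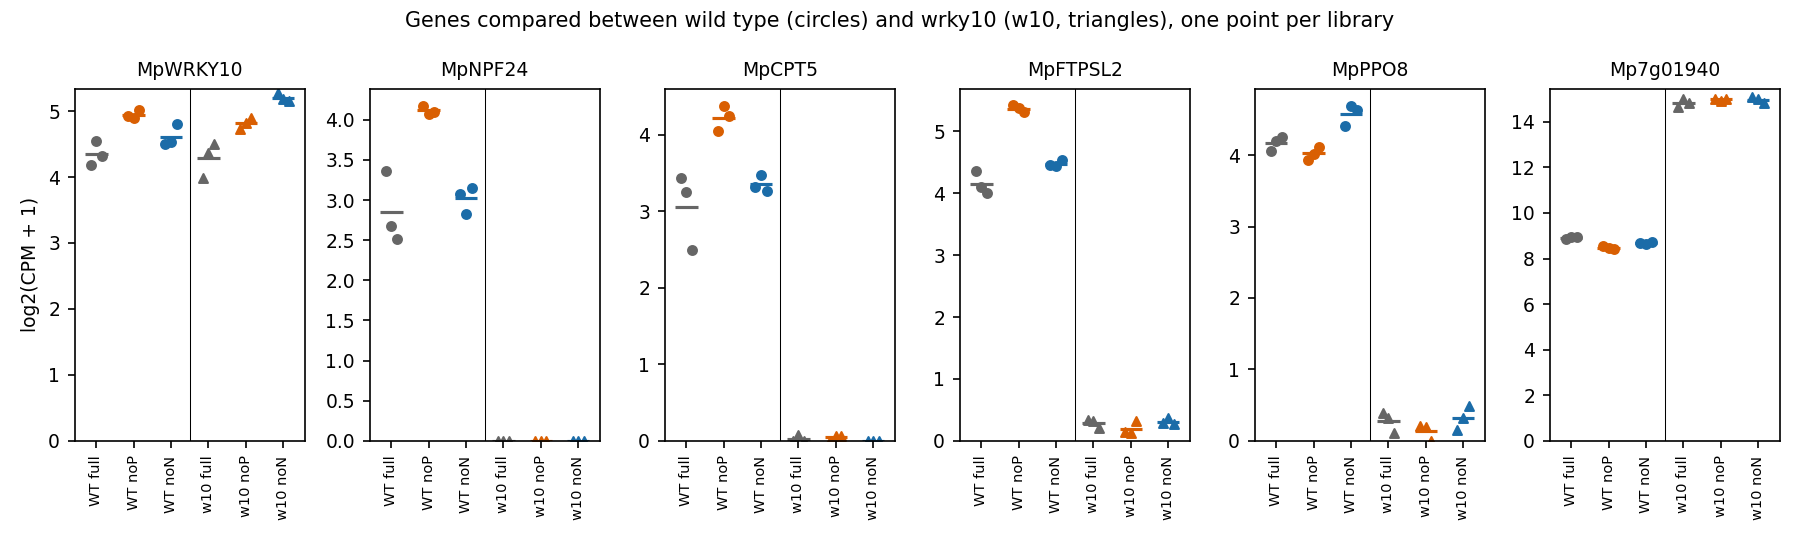
Level of MpWRKY10 and of genes that differed between genotypes in all 3 media, as log2(CPM + 1), in each Marchantia library. Wild type (WT) and Mpwrky10 (w10) are shown, and horizontal bars are group means. MpWRKY10 differed between genotypes only in the libraries labelled no nitrate. MpNPF24 had 0 counts in every mutant library in full medium and 6.48 ± 2.45 CPM in the wild type.

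Whether the mutant's response to a starvation differs from that of the wild type was tested as an interaction. For the libraries labelled no phosphate, 3 genes had a more positive and 37 a more negative response in the mutant, 1 and 11 of them at least 2-fold. MpCYP822-like7 had an interaction of log2 -1.21 (SE 0.131, adjusted p = 0.000266), MpPPO17 of -0.95 (SE 0.121), MpMTPSL8 of -0.80 (SE 0.115) and the kinase gene MpCTR1 of -0.65 (SE 0.125), while MpPPO32 had 1.04 (SE 0.203, adjusted p = 0.0376). Of the 37 genes, 18 rose in the wild type alone, 18 rose in both genotypes, and 1 rose in the wild type and fell in the mutant. Camera called 9 lists: histones and replication (0 of 41 members called, 0 adjusted over the list alone, median 0.16, adjusted p = 7.49e-05), P450 (2 of 85 lower, 2 adjusted over the list alone, adjusted p = 0.00209), terpene synthases (1 of 16 lower, 5 adjusted over the list alone, median -0.45, adjusted p = 0.00209) and dirigent genes (0 of 38, 0 adjusted over the list alone, adjusted p = 0.00742). The others were LEA (0 of 36, 1 adjusted over the list alone, adjusted p = 0.0122), oil-body markers (0 of 4, 2 adjusted over the list alone, adjusted p = 0.0322), autophagy (0 of 21, 0 adjusted over the list alone, median -0.10, adjusted p = 0.0403), antioxidant enzymes (0 of 23, 3 adjusted over the list alone, adjusted p = 0.0459) and other flavonoid enzymes (0 of 26, 3 adjusted over the list alone, adjusted p = 0.0478). These had adjusted p of 0.289 to 0.674 with an estimated correlation. The count of 40 was 154 with the DESeq2 Wald test and 70 with the replicate block, and it moved with single libraries. Without wild-type replicate 1, 2 or 3 in full medium it was 22, 16 and 62, and without wild-type replicate 1, 2 or 3 labelled no phosphate 15, 16 and 26. Without mutant replicate 1, 2 or 3 in full medium it was 93, 21 and 21, and without mutant replicate 1 or 3 labelled no phosphate 24 and 26.

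For the libraries labelled no nitrate, 122 genes had a more positive and 155 a more negative response in the mutant, but at 2-fold or more the balance turned, to 47 and 19. MpWRKY7 (log2 3.51, SE 0.859, adjusted p = 0.0406), the transcription factor gene MpERF15 (log2 2.88, SE 0.468, adjusted p = 0.00397), MpOMT15 (log2 2.65, SE 0.468), the pathogenesis-related genes MpPR6a (log2 2.53, SE 0.501) and MpPR6b (log2 2.40, SE 0.560), and MpWRKY10 itself (log2 0.67, SE 0.168, adjusted p = 0.0424) had a more positive response. The calls of MpWRKY7 and MpPR6b ended without a filter on low counts, and that of MpWRKY10 with DESeq2 size factors. MpPPO55 (log2 -1.79, SE 0.254), the transcription factor gene MpGARP6 (adjusted p = 0.000412), MpGDPD (log2 -1.28, SE 0.296) and MpUGT7 (log2 -1.10, SE 0.159) had a more negative one, and the call of MpGDPD ended without the filter. Of the 122 genes, 75 rose in the mutant alone and 30 in both genotypes, and of the 155 genes, 49 fell in the mutant alone and 47 rose in the wild type alone. Only the pathogenesis-related list was called of 41, with 2 of 16 members higher and 0 lower (2 and 0 adjusted over the list alone, median 2.15, camera adjusted p = 0.0405, adjusted p = 0.653 with an estimated correlation). The count of 277 was 132 without wild-type replicate 1 and 164 without replicate 2 in full medium, 151 and 160 without wild-type replicates 2 and 3 labelled no nitrate, and 162 without mutant replicate 2 labelled no nitrate. It was 159 when only these groups were fitted, but 416 with the replicate block and 565 with the DESeq2 Wald test.

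Whether both starvations move the same genes was asked next. In the wild type 1914 genes rose and 1157 fell under both, against 703.3 and 413.6 for independent lists of these sizes, and 116 moved in opposite directions. Both starvations share their controls, and in simulations of unchanged groups 0 genes were called in both. Across genes, which are not independent replicates, log2 fold changes had r = 0.699 and rho = 0.647, against a simulated r of 0.489, and a covariance of 0.585 against a simulated 0.0315. In the mutant 1699 rose and 1187 fell under both (612.9 and 352.9 for independent lists; r = 0.651 against 0.491; covariance 0.481 against 0.0351). The 3 controls cannot be split into parts of at least 2 libraries, so part of the excess may come from the shared controls. With separate controls, 2253 genes rose and 1835 fell in the libraries labelled no phosphate in both genotypes (692.5 and 499.6 for independent lists; r = 0.858), and 1983 rose and 1011 fell in those labelled no nitrate (622.4 and 292.1; r = 0.837).

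Lettuce shoots were asked the same questions, in a species whose identifiers were not paired with names. The nutrient labels of the lettuce libraries could therefore not be checked with marker genes, and all lettuce media are given as labelled. Without phosphate 5324 genes rose and 5527 fell, and 54.8% of all tested genes had no overlap between groups (10% by chance). The balance turned with other settings: 1835 rose and 1387 fell at least 2-fold, 5601 and 5094 without a filter on low counts, and 5024 and 4544, 4740 and 4266, and 6040 and 5877 without the first, the second and the third full-medium column. It also turned without replicate 3 labelled no phosphate (4826 and 4260). LOC111907445 was at 60.1 ± 9.56 CPM without phosphate and at 0 counts in full medium, at least 1170-fold higher, and LOC111878104 was at least 805-fold higher. LOC111881469 was lower, with a ratio of 163 (counting interval 28.8 to 6480), as was LOC111917852 (log2 -6.59, SE 1.77, adjusted p = 0.0228). Without nitrate 1612 genes rose and 1954 fell, and 32.6% of all tested genes had no overlap (10% by chance). The balance turned with other settings: 524 rose and 124 fell at least 2-fold, more genes rose than fell without the third full-medium column (2723 of 4905 rose), and 1760 rose and 1615 fell without a filter on low counts. It also turned when only these groups were fitted (1335 and 1209) and without the second column (1056 and 842) or replicate 1 labelled no nitrate (1136 and 848). LOC122195143 was higher, with a ratio of 40.2 (counting interval 13.4 to 198), as was LOC111884577 (log2 3.93, SE 0.648), though the call of LOC122195143 ended without the filter, while LOC111902813 was lower with a ratio of 665 (184 to 5500) and LOC111904853 at least 50.4-fold lower. The count of 3566 was 1898 without the second full-medium column, 1984 without replicate 1 labelled no nitrate and 2176 without replicate 2.

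Between the lettuce starvations, 3223 genes were higher and 3097 lower without nitrate than without phosphate, a balance that turned at 2-fold or more (517 and 792), and 47.7% of all tested genes had no overlap (10% by chance). LOC111907445 was at least 1210-fold lower and LOC111893952 at least 195-fold lower without nitrate, while LOC111878326 was higher, with a ratio of 82.3 (counting interval 22.4 to 686), as was LOC111917852 (log2 6.73, SE 1.75), whose call ended with the replicate number as a block. The count of 6320 was 4134 without replicate 2 labelled no nitrate. Both starvations raised 1318 and lowered 1722 genes, against 367.3 and 462.2 for independent lists, and 54 moved in opposite directions. The log2 fold changes had r = 0.634 against a simulated 0.503 and a covariance of 0.277 against 0.0285, with the same limit from the shared controls.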

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

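The tests of the nitrate-labelled libraries were written after their values were seen, and the tests of the interactions and the reassignments of library labels were written before theirs.

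The interactions called 40 genes for phosphate and 277 for nitrate. When genotype labels were reassigned within each medium, 7 of 100 assignments, the real one included, gave as many calls as the phosphate interaction, with up to 396 calls. For nitrate, 9 of 100 gave as many, with up to 1575. By this count alone chance cannot be excluded, but the count measures chance poorly. Of the other large assignments, 5 of 6 and 5 of 8 kept most libraries of one medium and exchanged most of the other, which adds the genotype difference up rather than subtracting it, a structure of the samples. The remaining 1 and 3 exchanged 5 of 6 mutant libraries, all of those in the starved medium and all but 1 in full medium. The genotype difference is then only partly subtracted, so it can add calls here too. The 83 assignments that mixed both genotypes in both media gave at most 0 calls for phosphate and 1 for nitrate, but they carry the genotype difference as spread within groups, which can hide calls. In the other comparisons the real labels gave the only assignment of 10 with as many calls, 1 in each, which is the smallest share these designs allow (0.1). The highest count from another assignment was 0, save 1 for phosphate in the mutant, 69 for nitrate in the mutant and 2 for genotype in the libraries labelled no nitrate.

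The first pattern was that phosphate transporter genes were higher in the Marchantia libraries labelled no nitrate and ammonium transporter genes higher in those labelled no phosphate. An exchange of the nutrient labels could explain it: the median of 5 other phosphate starvation markers was log2 0.903 between the libraries labelled no nitrate and no phosphate in the wild type, with 4 of 5 higher, and 0.429 in the mutant. The wider list of phosphate signalling and scavenging did not separate them as a whole (median 0.135, mean -0.0662, camera adjusted p = 0.879). Its members went both ways, with MpNLA far lower in the libraries labelled no nitrate. Camera looks for 1 shared direction, so this result counts neither for nor against exchanged labels. A single library exchanged between these 2 labels would not account for the pattern. Of the 6 libraries labelled no nitrate, over both genotypes, 0 had a summed PTB level inside the range of those labelled no phosphate. The PTB levels had been seen before, so this outcome was already known. An exchange with full medium cannot be seen this way for the libraries labelled no phosphate. Their sums of 27.0 to 34.9 CPM lay among those of full medium, 27.3 to 48.7 CPM. Nitrate removal itself could also raise phosphate transporters. The median of the ammonium transporters (-1.56) cannot tell this from exchanged labels, because phosphate shortage could raise ammonium transporters as well. An effect of nitrate removal would not account for markers no higher labelled no phosphate than in full medium. In the wild type the PTB sum was 33.7 against 37.5 CPM and MpSPX 71.8 against 76.3. MpGDPD was 79.5 against 112 and MpSQD 60.9 against 73.7 CPM, and in the mutant these were lower too. MpPAH was slightly higher in both genotypes, and MpPTB7 rose. In the libraries labelled no nitrate, autophagy genes were lower than labelled no phosphate in 9 of 21 cases and higher in 1 (wild type). In the mutant they were lower in 5 and higher in 0. Chlorophyll and photosynthesis genes were higher there in 4 and lower in 0 of 5 cases, and in the mutant in 2 and 1. Membrane lipid remodelling was called as a list in 1 comparison only, the wild type labelled no nitrate against full medium. The nutrients in the media were not measured in these files, so which label is right stays open.

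The second pattern was the nitrate interaction. Wild-type replicate 1 labelled no nitrate stood apart, and without it 165 of the 277 genes were still called, but the median size was log2 0.62 against 0.635 and 5 other libraries left fewer calls when removed (128 to 157). The lost calls therefore do not point to this library, though its part cannot be told apart from that of having fewer libraries. Wild-type replicate 3 in full medium, which also stood apart, was excluded as the source, with 204 still called. Without mutant replicate 3 in full medium, which lay apart the other way, 175 were. Without the gene Mp7g01940, 275 were still called, but TMM normalization trims a gene with such large ratios in any case. That outcome was therefore nearly given and is no separate test of a composition effect. All 277 genes kept their direction in every removal, which is nearly given because they were selected as called with all libraries.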

How the results depend on the processing

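The cause of each change below was not tested unless it is named, and fits without the abundant gene or without libraries that stood apart were added after results were seen. With the DESeq2 Wald test the interactions gave 154 genes for phosphate and 565 for nitrate, against 40 and 277. Entering the replicate number as a block gave 70 and 416. Same-numbered libraries did not all correlate above 0.1 in any comparison, with a lowest value of -0.28 for genotype in full medium, so no pairing was assumed. A shared effect of the replicate number is not excluded by this. For genotype labelled no nitrate the values were 0.22, 0.21 and 0.059, and all 3 libraries matched their own number best. For lettuce phosphate and lettuce nitrate alone, no paired analysis was made because the full-medium columns carry numbers other than the titles' replicate numbers. Fitting only the groups compared gave 280 genes for genotype in full medium and 159 for the nitrate interaction. A 2-fold minimum, which removes small changes by construction, left 1385 and 1108 genes for phosphate and nitrate in the wild type, 1000 and 1227 in the mutant, and 676 between the wild-type starvations. It left 173, 237 and 499 for genotype in full medium, labelled no phosphate and labelled no nitrate, 12 and 66 for the interactions, and 3222, 648 and 1309 for the lettuce phosphate, nitrate and direct comparisons. Shared responses fell to 731 in the wild type, 614 in the mutant and 465 in lettuce. Leaving out 1 library gave 5534 to 6000 genes for phosphate and 3362 to 4275 for nitrate in the wild type, 3805 to 4641 and 4148 to 4802 in the mutant, and 3278 to 3627 between the wild-type starvations. For genotype it gave 265 to 539 in full medium, 352 to 861 labelled no phosphate and 1635 to 2236 labelled no nitrate, and for the interactions 15 to 93 and 132 to 331. Lettuce gave 9000 to 11917 for phosphate, 1898 to 4905 for nitrate and 4134 to 5690 for the direct comparison. Without both wild-type libraries that stood apart the phosphate interaction gave 93. Camera called 89 lists with the preset correlation and 0 with an estimated one, while fry called 166. Named results, 587 in all, were recomputed under 4 settings and not with single libraries left out. DESeq2 size factors ended 1 call and added 1, and the DESeq2 Wald test, which gave no value for 2, ended 1 and added 15. Omitting the filter on low counts ended 11 and added 1. The block, which could not be entered for the 8 of lettuce phosphate and nitrate, ended 3 and added 1. None of the named results changed direction under these 4 settings.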

Other observations

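The tests of neighbouring genes and of mislabelled libraries were written after the set of genes below was seen, and the composition test before.

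A set of 200 genes differed between the mutant line and the wild type in all 3 media, 61 higher and 139 lower, and 94 of them changed at least 2-fold in each. Of the set, 37 lay next to another member on the chromosome, against a mean of 4.45 (0 to 10) for random genes and 5.36 (0 to 12) for random genes called in both starvations (permutation p = 1e-04, the smallest value possible with 10000 draws). Some runs of neighbours went one way, such as 8 loci from Mp3g09170 to Mp3g09240, all lower, with MpNPF9 among them. Others were of mixed direction, such as 5 loci from Mp7g12360 to Mp7g12400 (log2 -0.849 to 8.57 in full medium) and 3 from Mp3g18500 to Mp3g18520 with MpMTPSL2 and MpCPT5 (log2 -8.46 to 2.75). A chromosomal or strain difference of the mutant line could explain such runs, though clustered genes under one or several regulators may give them too, and this stays open. Without Mp7g01940, 197 of the 200 were still called. TMM normalization trims genes with such large ratios in any case, so this outcome was nearly given and is no separate test of a composition effect. For the level of Mp7g01940, 0 of 18 libraries lay inside the range of the other genotype. That gene was picked after its separation was seen, so this outcome was already known. It concerns the genotype label only, not the media.

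Some lists were called in no Marchantia comparison by camera at the preset correlation, 14 of 41. The nearest were ABCG transporters (lowest adjusted p = 0.0627), shikimate and phenylalanine supply (0.0763) and NAC transcription factors (0.0791), and bHLH factors were furthest (0.479). The list of phosphate signalling and scavenging had members of both directions in the wild type labelled no phosphate, with MpNLA at log2 1.89 and MpLPR11 at -1.49, and a lowest adjusted p of 0.11. Genes with 0 or few reads in the mutant were rare: 3 genes had at most 3 counts in all its libraries and at least 1 CPM in every wild-type library, among them MpCPT5 and MpNPF24, and 0 genes had the reverse. No deletion can be read from this, as a silent gene gives the same counts.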
